A study of Mus musculus with 10 samples.

How the data were processed

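The series holds RNA-seq of sorted mouse bone-marrow progenitors: 10 libraries in 5 groups of 2. Total RNA was extracted with peqGOLD TriFast, and libraries were made with the TruSeq V2 LT or the NEBNext Ultra kit, without a record of which library had which kit. The deposited table gives RPKM (rpkm, reads scaled by gene length and by the reads of the library) for 23240 genes in each library, as computed by the authors. Per the file headers it also gives the p-value and the FDR-corrected p-value of Baggerley's test between each 2 groups. The genome build was mm9 per the submitters' processing notes, and the aligner and the read counter are not given in the sources used here. Groups were taken from the sample labels, and lane and library numbers from the column headers of the table. Only the deposited table was used here; raw reads were not analysed here.

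The plan held a branch for counts and a branch for normalized values, and the latter was followed because the unit is RPKM. Genes with at least 1 RPKM in at least 2 libraries were kept (10905 of 23240), and log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on all 10 libraries, with 1 mean per group and 5 residual degrees of freedom. Contrasts were Runx1-deleted minus wild type in GMP and in MEP, the difference of these 2 effects, XMP minus Runx1-deleted GMP, XMP minus Runx1-deleted MEP, and wild-type GMP minus wild-type MEP. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Genes of XMP beyond both other Runx1-deleted groups were those called in both contrasts with the same sign, beside simulated unchanged groups and independent lists of the same sizes, since the 2 contrasts share the XMP libraries. The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

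Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over 19 lists and 6 contrasts (114 pairs). The lists were granule and neutrophil; monocyte, macrophage and dendritic cell; myeloid regulators and cytokine receptors; erythroid; megakaryocyte and platelet; stem and multipotent progenitor; mast cell, basophil and eosinophil; lymphoid; stromal and endothelial; RUNX genes and partners; sort marker; S phase; G2 and M phase; ribosome biogenesis; interferon response; NF-kB and inflammatory; immediate early and heat shock; p53 target and apoptosis; and sex-linked genes. A list of mitochondrially encoded genes was planned too, but the table holds none of its members. Current symbols were matched to those of the table (Spi1 to Sfpi1, Chil3 to Chi3l3, Hbb-bs to Beta-s, Ifi27 to Ifi27l1). List members past the gene test were counted over all genes and adjusted over the list alone.

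Named genes were, for each of 4 contrasts, the 10 largest rises and the 10 largest falls among called genes with groups that do not overlap and a mean of at least 5 RPKM, up to 4 list members in each direction with the smallest p, and the RUNX and sort marker genes; the text prints a selection of these, and a few genes that met the rules are not reported here. The position of XMP was (XMP - MEP)/(GMP - MEP) on group means of log2 values in Runx1-deleted libraries, over genes that differ at least 4-fold between wild-type GMP and MEP and at least 2-fold in the same direction between the Runx1-deleted ones. The overlap of effects was compared with the product of the 2 shares, and correlations were taken across genes, which are not replicates.

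Depth was worked back from the RPKM values. For 19335 genes all values of the 10 libraries were whole reads within 0.01 read, for 1 gene they were not, and 3904 genes were at 0 throughout. The length of 953 genes was settled with a gene annotation. The totals behind the RPKM values were 20.8 to 54.9 M reads per library, of which 75.3% to 83.3% were recovered in genes, so that 1 read in a gene of 1 kb equals 0.0182 to 0.0480 RPKM. Recovery of reads was tested on simulated data with known totals (1000 of 1000 genes right). The totals themselves and the lengths settled with the annotation were not tested. The test itself was also tested on simulated data with the same spread in each group, no length trend, and changes only in genes above about 5 RPKM. Of 100 genes changed 2-fold 70 to 74 were called, and of 100 changed 4-fold 99 or 100. The other genes gave 8 to 14 false calls. The real groups differed in spread and in length trend, so these rates need not hold for them. Replicates correlated at 0.968 (wild-type MEP) to 0.994 (Runx1-deleted GMP), and the highest correlation between libraries of different groups was 0.973, above that of the wild-type MEP replicates. Near-identical paralogs such as Hba-a1 and Hba-a2, or Hbb-b1 and Beta-s, share reads, so their separate levels are uncertain.

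Alternatives were quantile normalization, limma without trend, no filter, a mean of at least 5 RPKM, a pseudocount of 0.1, only the groups compared, a block for the replicate or for the library set (numbers 25 to 29 against 30 to 34), an absolute log2 fold change of at least 1, and leaving out each library, where the lone library of a group is assumed to vary like the others. Quantile normalization moved the median of all genes by -0.06 to -0.004 (log2). Chosen after seeing the data were voom on the recovered reads, a weight for each group, lanes 4 and 5 alone, and removal of the trend of each library with gene length (lowess, span 0.3). Without removal a simulated length trend, with the same slope in each library of lanes 2 and 3, gave 148 false calls, and with it 8. The real slopes of these libraries differed (-0.13 and -0.19 in wild-type GMP, -0.37 in wild-type MEP replicate 1), as did the spread of the groups. These counts need not hold for the real data. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.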

Results

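RNA was sequenced from bone-marrow progenitors of mice carrying the vav-Cre transgene with intact Runx1 (wild type) or with floxed Runx1 alleles (Runx1-deleted). Cells were sorted as lin- sca- kit+ CD41- CD105- and split by CD16/32 and CD150 into GMP (CD16/32+ CD150-), MEP (CD16/32- CD150+) and XMP (CD16/32+ CD150+). The 5 groups hold 2 libraries each. The read totals behind the RPKM values were 39.9 and 20.8 M in wild-type GMP, 54.9 and 46.1 M in Runx1-deleted GMP and 36.4 and 45.4 M in wild-type MEP. Runx1-deleted MEP held 37.3 and 42.3 M, and XMP, sorted from Runx1-deleted marrow alone, 41.9 and 43.6 M. Levels are mean ± SD in RPKM with n = 2 libraries per group, and fold changes are log2 ± SE. List medians are log2 fold changes tested with camera, and other p-values come from limma over 10905 genes unless another test is named. Nothing in the labels says that the 2 libraries of a group come from separate animals, so the p-values measure only the spread between libraries. Fold changes were taken on log2(RPKM + 1), which understates changes of genes with low levels.

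The level of Runx1 itself was higher, not lower, in the Runx1-deleted groups. Wild-type GMP held 28.5 and 26.9 RPKM against 63.0 and 72.3 in Runx1-deleted GMP. Wild-type MEP held 17.2 and 25.5 against 41.5 and 36.8 in Runx1-deleted MEP, and XMP 85.9 and 78.5. RPKM of the whole gene does not check the deletion of an exon. In GMP Runx1 rose (log2 1.26 ± 0.20, adjusted p = 0.00306). In MEP it rose as well (log2 0.87 ± 0.20, adjusted p = 0.0215). That call was lost without wild-type MEP replicate 1 (adjusted p = 0.0950), Runx1-deleted MEP replicate 1 (0.119) or replicate 2 (0.0759). It was also lost with only the groups compared (0.149), group weights (0.163), lanes 4 and 5 alone (0.1002) or the length trend removed (0.0521). Of 18 tested RUNX genes and partners 2 rose and 0 fell in GMP, adjusted over the list alone 2 and 1, and 2 rose and 3 fell in MEP. Cbfb, the partner subunit of RUNX proteins, fell in MEP from 53.3 ± 3.88 to 27.2 ± 1.95 RPKM (log2 -0.94 ± 0.17, adjusted p = 0.00548; 0.0550 without Runx1-deleted MEP replicate 2, 0.0656 with only the groups compared and 0.0988 with group weights). The list as a whole passed in neither genotype comparison (adjusted p = 0.481 in GMP and 0.733 in MEP).

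Transcripts of the sorting markers followed the gates in part. Slamf1, which encodes CD150, was 0.109 ± 0.022 RPKM in wild-type GMP, 9.49 ± 0.791 in wild-type MEP, 27.3 ± 3.69 in Runx1-deleted MEP and 30.9 ± 0.05 in XMP. Of the genes for CD16 and CD32, Fcgr3 was 59.7 ± 2.24 RPKM in Runx1-deleted GMP and 1.88 ± 0.335 in XMP, whereas Fcgr2b was 64.7 ± 6.35 and 66 ± 11. Itga2b, which encodes CD41, was 31.4 ± 4.48 RPKM in wild-type GMP, 148 ± 21 in wild-type MEP and 667 ± 21.5 in XMP, although all gates were CD41-. Kit was 67.6 ± 3.43 RPKM in wild-type GMP and 124 ± 19.6 in Runx1-deleted MEP.

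Long and short genes differed between the libraries together with the sequencing lane. The median deviation of the longest genes (4444 to 23495 bp) minus that of the shortest (183 to 1479 bp) was -0.33 and -0.43 (log2) in wild-type GMP (lanes 3 and 2), and 0.32 and 0.23 in Runx1-deleted GMP (lane 5). It was -1.02 and 0.14 in wild-type MEP (lanes 3 and 5), -0.003 and 0.31 in Runx1-deleted MEP (lane 5), and 0.27 and 0.57 in XMP (lanes 5 and 4). Across genes the Spearman correlation of the Runx1 effect with gene length was 0.55 in GMP and 0.53 in MEP. Each genotype comparison below is therefore also given with the length trend removed. In GMP the lane coincides with the genotype, so no comparison within a lane exists.

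**Figure D1:**
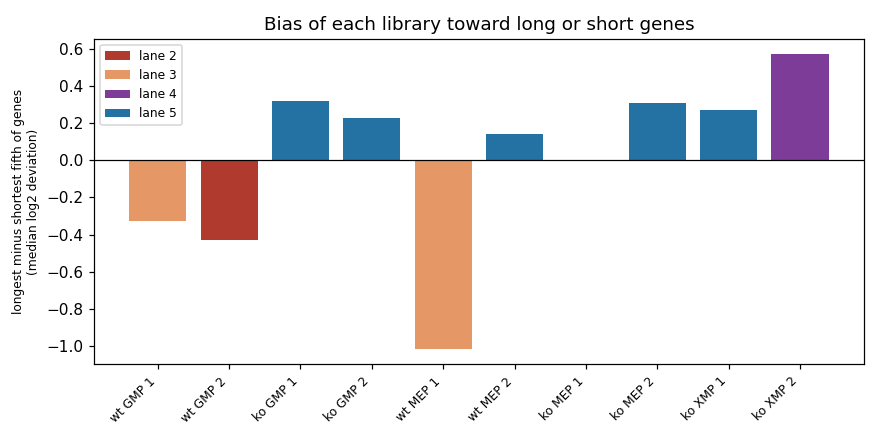
Median log2 deviation of the longest genes (4444 to 23495 bp) minus that of the shortest (183 to 1479 bp) in each of the 10 libraries, coloured by sequencing lane. The libraries of lanes 2 and 3, all wild type, are negative, and those of lanes 4 and 5 are near 0 or positive.

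The comparison of wild-type GMP with wild-type MEP asks how far the 2 gates separate known lineages. GMP carried the myeloid granule proteins. Mpo, myeloperoxidase, was 5281 ± 514 RPKM in GMP and 12.4 ± 0.832 in MEP (log2 8.62 ± 0.23, adjusted p = 3.42e-09). Ctsg, cathepsin G, was 2116 ± 228 and 4.89 ± 0.331 (log2 8.49 ± 0.18, adjusted p = 7.39e-10). Cebpa, a transcription factor of granulocyte and monocyte progenitors, was 119.9 ± 18 and 5.32 ± 0.305 (log2 4.25 ± 0.18, adjusted p = 3.70e-08). MEP carried the higher levels of Aqp1, a water channel of red cells (log2 -5.97 ± 0.25, adjusted p = 3.85e-08), and of the platelet genes Treml1 (log2 -4.24 ± 0.21, adjusted p = 1.05e-07) and Gp5 (log2 -4.54 ± 0.18, adjusted p = 2.91e-08). Of the granule list 23 of 26 tested members were higher in GMP and 0 lower (median 2.80, adjusted p = 5.60e-25, adjusted p = 0.0647 with an estimated correlation). Of the monocyte and macrophage list 19 of 22 were higher (median 3.22, adjusted p = 1.11e-20, adjusted p = 0.189 with an estimated correlation). Of the myeloid regulators 19 of 25 were higher and 1 lower (median 2.13, adjusted p = 3.51e-14, adjusted p = 0.0647 with an estimated correlation). Of the mast cell, basophil and eosinophil list 20 of 28 were higher and 4 lower (median 1.79, adjusted p = 1.09e-11, adjusted p = 0.189 with an estimated correlation). Of the erythroid list 28 of 44 were lower in GMP and 0 higher (median -2.15, adjusted p = 4.28e-21, adjusted p = 0.189 with an estimated correlation). Of the megakaryocyte list 28 of 40 were lower (median -2.02, adjusted p = 2.99e-19, adjusted p = 0.246 with an estimated correlation). Of the stem cell list 17 of 34 were lower and 5 higher (median -0.70, adjusted p = 0.00347, adjusted p = 0.395 with an estimated correlation). Lymphoid genes were higher in GMP (median 0.57, adjusted p = 0.00587, adjusted p = 0.32 with an estimated correlation; 0.136 without wild-type MEP replicate 2), as were NF-kB genes (median 0.53, adjusted p = 0.00187, adjusted p = 0.395 with an estimated correlation). Interferon genes were lower (median -0.40, adjusted p = 0.0101, adjusted p = 0.591 with an estimated correlation; 0.108 without wild-type MEP replicate 1).

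In that comparison 2352 genes differed (1280 higher and 1072 lower in GMP; 3437 at an unadjusted p under 0.05). Without wild-type MEP replicate 1 the split was 1224 higher and 1972 lower, and without wild-type MEP replicate 2 it was 2144 and 1171.

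**Figure D2:**
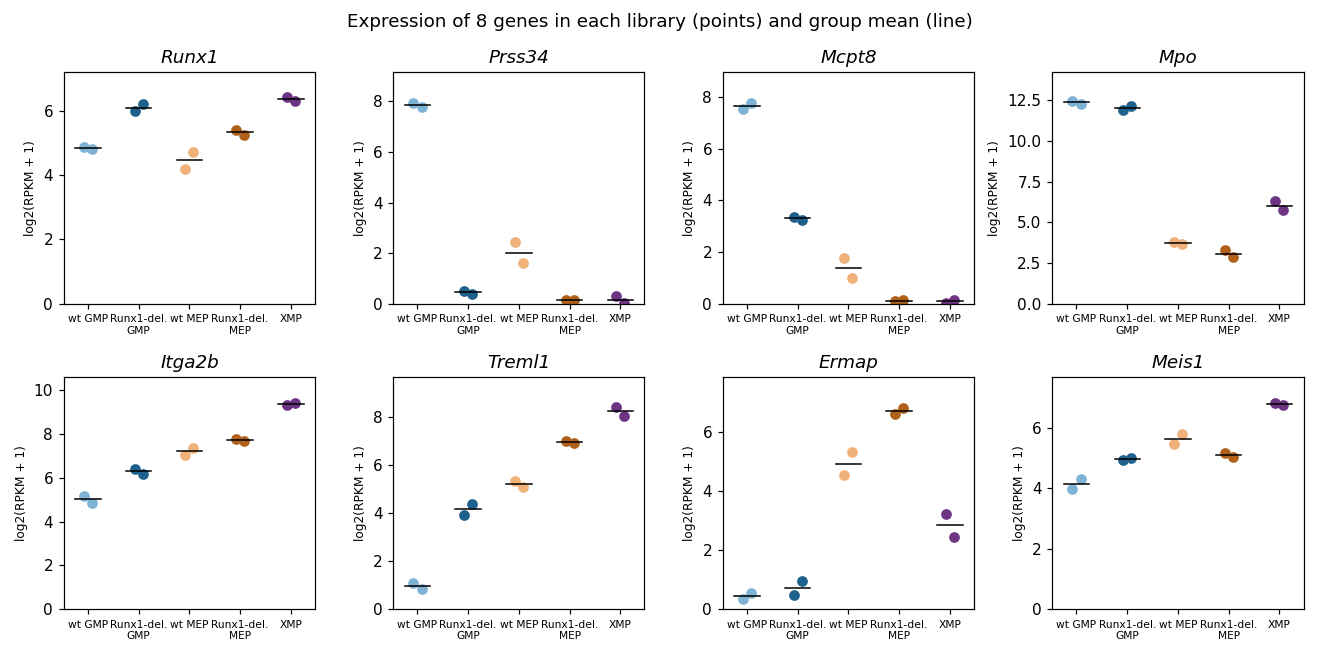
Log2(RPKM + 1) of Runx1, Prss34, Mcpt8, Mpo, Itga2b, Treml1, Ermap and Meis1 in each library (points) with the group mean (line), for the 5 groups. Prss34 is near the floor and Mcpt8 far lower than in wild type in Runx1-deleted GMP, and Itga2b, Treml1 and Meis1 are highest in XMP.

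Runx1-deleted and wild-type GMP were compared to ask what the loss of Runx1 changes in this gate. Genes of mast cells and basophils were among those that fell most. Prss34, a protease of basophils and mast cells, fell from 231 ± 16.9 to 0.369 ± 0.093 RPKM (log2 -7.41 ± 0.25, adjusted p = 7.34e-08). Mcpt8, a protease of basophils, fell from 199.9 ± 24.5 to 8.9 ± 0.558 (log2 -4.34 ± 0.24, adjusted p = 2.74e-06). Gzmb, a granule protease, fell from 39.6 ± 8.77 to 0.255 ± 0.058 (log2 -5.0 ± 0.17, adjusted p = 7.34e-08). Fcer1a, the IgE-binding chain of the high-affinity receptor, fell from 11 ± 1.1 to 0.053 ± 0.075 (log2 -3.51 ± 0.18, adjusted p = 2.30e-06). Cd63, a tetraspanin of granule membranes, fell from 428 ± 59.3 to 86.9 ± 33.6 (log2 -2.33 ± 0.27, adjusted p = 0.000552). Against this direction Cd200r3 rose from 1.04 ± 0.277 to 5.89 ± 0.332 (log2 1.76 ± 0.15, adjusted p = 7.89e-05). Of the 28 tested members 12 fell and 2 rose. Adjusted over the list alone 17 fell and 4 rose (median -0.92, adjusted p = 7.26e-10, adjusted p = 0.189 with an estimated correlation). Outside the lists Scin, an actin-severing protein, fell from 16.8 ± 3.87 to 0.181 ± 0.041 RPKM (log2 -3.90 ± 0.24, adjusted p = 5.19e-06).

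Granulocyte and monocyte genes fell too in Runx1-deleted GMP. Cebpa fell from 119.9 ± 18 to 46.4 ± 3.84 RPKM (log2 -1.35 ± 0.18, adjusted p = 0.00108). Fcnb, a ficolin, fell from 13.6 ± 4.24 to 2.82 ± 0.453 (log2 -1.90 ± 0.20, adjusted p = 0.000297) and Prss57 from 58.1 ± 12.2 to 16.5 ± 2.56 (log2 -1.75 ± 0.20, adjusted p = 0.00044). Mpo stood at 5281 ± 514 and 4144 ± 568 RPKM (log2 -0.35 ± 0.23, adjusted p = 0.366). Of 26 granule genes 5 fell and 0 rose, adjusted over the list alone 12 and 0 (median -0.57, adjusted p = 4.72e-08, adjusted p = 0.189 with an estimated correlation). Among monocyte genes Ly6c2, a surface antigen of inflammatory monocytes, fell from 569 ± 87.7 to 81.2 ± 6.7 (log2 -2.79 ± 0.30, adjusted p = 0.0003). H2-Ab1, an MHC class II chain, fell from 81.5 ± 6.64 to 32.6 ± 6.39 (log2 -1.31 ± 0.19, adjusted p = 0.00224). F13a1, the A chain of coagulation factor XIII, rose from 74.6 ± 15 to 228 ± 24.2 (log2 1.61 ± 0.24, adjusted p = 0.00243; 0.0510 without wild-type GMP replicate 2). Of 22 monocyte genes 8 fell and 1 rose, adjusted over the list alone 10 and 1 (median -0.44, adjusted p = 8.74e-05, adjusted p = 0.47 with an estimated correlation).

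Megakaryocyte and platelet genes rose in Runx1-deleted GMP. Treml1, a receptor of platelet granules, rose from 0.948 ± 0.229 to 17.2 ± 4.12 RPKM (log2 3.21 ± 0.21, adjusted p = 6.34e-06). F2r, a thrombin receptor, rose from 3.49 ± 0.291 to 36.3 ± 2.99 (log2 3.05 ± 0.17, adjusted p = 2.74e-06). Gp5, a platelet glycoprotein, rose from 0.814 ± 0.129 to 11.4 ± 1.58 (log2 2.77 ± 0.18, adjusted p = 6.49e-06). Selp, P-selectin, rose from 2.93 ± 0.649 to 18.9 ± 3.25 (log2 2.34 ± 0.22, adjusted p = 0.000122) and Itga2b from 31.4 ± 4.48 to 78 ± 9.08 (log2 1.29 ± 0.19, adjusted p = 0.00211). Of 40 tested members 12 rose and 1, Serpine2, fell. Adjusted over the list alone 15 rose and 1 fell (median 0.59, adjusted p = 1.07e-07, adjusted p = 0.459 with an estimated correlation). Of 34 stem and multipotent progenitor genes 9 rose, Tek among them (from 0.798 ± 0.313 to 6.88 ± 0.264; log2 2.14 ± 0.21, adjusted p = 0.000165). In that list 1 member, Ifitm1, fell (from 144 ± 24 to 44 ± 4.89; log2 -1.68 ± 0.27, adjusted p = 0.00326). Adjusted over the list alone 14 stem cell genes rose and 2 fell (median 0.31, adjusted p = 0.0164, adjusted p = 0.47 with an estimated correlation; adjusted p = 0.0695 without wild-type GMP replicate 1).

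Globin transcripts were higher in Runx1-deleted GMP, while the erythroid list as a whole did not pass. Beta-s, an adult beta globin, rose from 41.3 ± 14.2 to 303 ± 104 RPKM (log2 2.84 ± 0.34, adjusted p = 0.000666). Hba-a1, an alpha globin, rose from 14.9 ± 5.2 to 117 ± 48.8 (log2 2.88 ± 0.36, adjusted p = 0.000799). Reads of near-identical globin paralogs cannot be assigned well. Slc4a1, the anion exchanger of red cells, rose from 0.062 ± 0.013 to 1.95 ± 0.179 (log2 1.47 ± 0.16, adjusted p = 0.000283). Klf1, a transcription factor of red-cell precursors, was 4.47 ± 1.5 and 2.11 ± 0.716 RPKM (log2 -0.81 ± 0.26, adjusted p = 0.108). Of 44 tested members 7 rose and 1 fell, adjusted over the list alone 9 and 4 (median 0.18, adjusted p = 0.0903, adjusted p = 0.817 with an estimated correlation). The fall was that of Car1, carbonic anhydrase 1 (log2 -2.32 ± 0.40, adjusted p = 0.00559; 0.113 without wild-type GMP replicate 2 and 0.0708 without Runx1-deleted GMP replicate 1).

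Interferon response genes also rose in Runx1-deleted GMP, with 7 of 39 higher and 0 lower, adjusted over the list alone 14 and 0 (median 0.45, adjusted p = 1.31e-06, adjusted p = 0.315 with an estimated correlation). Oas2, a synthetase of the antiviral RNase L pathway, rose from 0.827 ± 0.309 to 8.02 ± 0.631 RPKM (log2 2.31 ± 0.31, adjusted p = 0.00121), and Oas3 from 1.82 ± 0.543 to 9.15 ± 1.83 (log2 1.85 ± 0.21, adjusted p = 0.000401). Of 9 sort marker genes 2, Itga2b and Slamf1, rose, Slamf1 by 0.96 ± 0.19, adjusted p = 0.0114. The call of Slamf1 was lost without any 1 of the 4 GMP libraries (adjusted p from 0.0514 to 0.173). Adjusted over the list alone 5 rose and 1 fell (median 0.53, adjusted p = 0.027, adjusted p = 0.266 with an estimated correlation; adjusted p = 0.0847, 0.0744 and 0.0790 without wild-type GMP replicate 1, wild-type MEP replicate 1 and wild-type MEP replicate 2). The other lists did not pass: adjusted p was 0.735 for myeloid regulators, 0.242 for lymphoid, and 0.996 for stromal and endothelial genes. It was 0.506 for NF-kB and inflammatory, 0.467 for p53 target and 0.433 for sex-linked genes. For cell cycle and growth it was 0.409 for S phase, 0.854 for G2 and M phase, 0.854 for ribosome biogenesis and 0.352 for immediate early and heat shock genes. The direction of 3 of these tests differed from the sign of the mean: G2 and M phase (down, median -0.04 and mean 0.08), stromal and endothelial (down, -0.05 and 0.10) and sex-linked genes (down, -0.47 and 0.23). In the sex-linked list Xist, the RNA that coats the inactive X chromosome, rose from 5.72 ± 5.92 to 80.0 ± 30.9 (log2 3.89 ± 0.88, adjusted p = 0.0269; 0.367, 0.198 and 0.0860 without wild-type GMP replicate 2, Runx1-deleted GMP replicate 1 and replicate 2, and 0.133 with no filter).

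In GMP 569 genes changed, 343 higher and 226 lower in Runx1-deleted cells (2486 at an unadjusted p under 0.05). The count was 233 without wild-type GMP replicate 2 (116 higher and 117 lower), 248 and 269 without Runx1-deleted GMP replicates 1 and 2, and 1724 and 1729 without wild-type MEP replicates 1 and 2. With the length trend removed 709 genes were called and 88.0% of the 569 kept their call. All lists called in GMP passed again, and the erythroid list passed too (adjusted p = 0.00696). The granule median moved from -0.57 to -0.30 (4 members lower), and 16 interferon genes were called higher in place of 7.

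In MEP the same comparison gave higher erythroid genes and lower myeloid genes in Runx1-deleted cells. Rhag, a Rh-associated membrane protein of red cells, rose from 4.77 ± 1.06 to 30.3 ± 3.04 RPKM (log2 2.45 ± 0.21, adjusted p = 7.21e-05). Epb4.2, a protein of the red-cell membrane skeleton, rose from 0.445 ± 0.07 to 2.55 ± 0.25 (log2 1.30 ± 0.13, adjusted p = 0.000173). Ermap, an erythroid membrane protein, rose from 30.8 ± 11.9 to 106 ± 10.3 (log2 1.81 ± 0.31, adjusted p = 0.00489; 0.0708 in lanes 4 and 5 alone and 0.0896 with group weights). Klf1 was 108 ± 20.8 and 132 ± 29.1 RPKM (log2 0.29 ± 0.26, adjusted p = 0.547). Of 44 erythroid genes 17 rose and 0 fell, adjusted over the list alone 23 and 1 (median 0.58, adjusted p = 9.66e-10, adjusted p = 0.288 with an estimated correlation).

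Megakaryocyte genes moved in both directions in Runx1-deleted MEP. Thbs1, thrombospondin 1, rose from 1.87 ± 0.222 to 54.2 ± 4.22 RPKM (log2 4.27 ± 0.44, adjusted p = 0.000166). Alox12, the platelet 12-lipoxygenase, rose from 0.605 ± 0.054 to 22.2 ± 4.34 (log2 3.84 ± 0.36, adjusted p = 0.000101). Clec1b, the platelet receptor CLEC-2, rose from 3.96 ± 0.048 to 38.9 ± 5.32 (log2 3.0 ± 0.27, adjusted p = 8.01e-05). Treml1 rose from 35.8 ± 4.41 to 125 ± 5.74 (log2 1.78 ± 0.21, adjusted p = 0.000376). Serpine2, a thrombin inhibitor, fell from 30.7 ± 6.72 to 4.49 ± 0.139 (log2 -2.51 ± 0.23, adjusted p = 9.55e-05). Of 40 members 14 rose and 5 fell, adjusted over the list alone 18 and 7 (median 0.44, adjusted p = 0.000822, adjusted p = 0.65 with an estimated correlation). Outside the lists Podxl, a sialomucin, rose from 1.12 ± 0.277 to 21.2 ± 6.37 (log2 3.36 ± 0.22, adjusted p = 1.91e-05). The protease Hpn rose from 2.27 ± 0.147 to 39.3 ± 4.65 (log2 3.62 ± 0.20, adjusted p = 5.61e-06).

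Myeloid genes fell in Runx1-deleted MEP, where most members of the granule, monocyte and mast cell lists started at lower levels than in GMP. Of the mast cell, basophil and eosinophil list 4 of 28 members stood higher in wild-type MEP than in wild-type GMP. Cebpa fell from 5.32 ± 0.305 to 0.85 ± 0.012 RPKM (log2 -1.77 ± 0.18, adjusted p = 0.000142). Nkg7, a granule membrane protein, fell from 149.7 ± 39.4 to 6.1 ± 2.85 (log2 -4.44 ± 0.31, adjusted p = 2.15e-05) and Prss34 from 3.21 ± 1.62 to 0.104 ± 0.009 (log2 -1.88 ± 0.25, adjusted p = 0.00082). Csf3r, the G-CSF receptor, rose from 1.68 ± 0.622 to 8.67 ± 1.22 (log2 1.86 ± 0.24, adjusted p = 0.000675). Of 26 granule genes 6 fell and 0 rose, adjusted over the list alone 9 and 0 (median -0.36, adjusted p = 6.50e-07, adjusted p = 0.195 with an estimated correlation). Of 22 monocyte genes 4 fell and 1 rose, adjusted over the list alone 6 and 2 (median -0.42, adjusted p = 0.000909, adjusted p = 0.541 with an estimated correlation). Of 28 mast cell, basophil and eosinophil genes 8 fell and 4 rose, adjusted over the list alone 11 and 4 (median -0.39, adjusted p = 0.000975, adjusted p = 0.395 with an estimated correlation). Of 25 myeloid regulators 4 rose and 5 fell, and the list did not pass (adjusted p = 0.179).

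Other lists called in MEP were lower, apart from the interferon response. Among stem cell genes Ifitm1 fell from 134 ± 47.3 to 10.8 ± 3.09 RPKM (log2 -3.49 ± 0.27, adjusted p = 3.17e-05). Ltb, lymphotoxin beta, fell from 9.65 ± 2.75 to 1.69 ± 0.133 (log2 -1.96 ± 0.26, adjusted p = 0.000971). Of 34 members 7 fell and 3 rose, adjusted over the list alone 13 and 3 (median -0.29, adjusted p = 0.0218, adjusted p = 0.50 with an estimated correlation; adjusted p = 0.0669 and 0.0697 without wild-type MEP replicates 1 and 2). Of 12 lymphoid genes 1 fell and 1 rose, adjusted over the list alone 8 and 1 (median -0.59, adjusted p = 0.000655, adjusted p = 0.278 with an estimated correlation). Of 6 stromal and endothelial genes 3 fell, among them Pdgfrb, a growth factor receptor of pericytes (from 6.47 ± 1.08 to 0.816 ± 0.308; log2 -2.04 ± 0.21, adjusted p = 0.000155). Kdr, a receptor of endothelial cells, rose (from 1.35 ± 0.208 to 7.0 ± 0.388; log2 1.77 ± 0.18, adjusted p = 0.000159). That list was lower as a whole (median -0.68, adjusted p = 0.0116, adjusted p = 0.315 with an estimated correlation; 0.0872 without wild-type MEP replicate 2). Of 39 interferon genes 9 rose and 1 fell, adjusted over the list alone 12 and 3 (median 0.29, adjusted p = 0.000415, adjusted p = 0.459 with an estimated correlation; 0.125 without wild-type MEP replicate 2). Of 21 immediate early and heat shock genes 2 fell and 1 rose (median -0.40, adjusted p = 0.00556, adjusted p = 0.547 with an estimated correlation; 0.235 without wild-type MEP replicate 1). Adjusted p was 0.446 for S phase, 0.0919 for G2 and M phase, 0.271 for ribosome biogenesis, 0.837 for NF-kB, 0.984 for p53 target, 0.488 for sort marker and 0.152 for sex-linked genes. In 3 of these the direction of the test differed from the sign of the median or mean: sort markers (up, median -0.22 and mean 0.18), NF-kB (down, 0.02 and -0.04) and p53 (down, -0.11 and 0.00).

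The count in MEP lay above that in GMP (569) with 1 spread shared by all groups. It lay below with only the groups compared (340 against 1925) and with group weights (219 against 2023). In the shared fit 872 genes changed in MEP, 433 higher and 439 lower (2408 at an unadjusted p under 0.05). The count was 361 and 449 without Runx1-deleted MEP replicates 2 and 1, and 3427 without wild-type MEP replicate 2, with 2389 higher and 1038 lower. Without wild-type MEP replicate 1 the split was 252 higher and 384 lower. With the length trend removed 1056 genes were called and 86.5% of the 872 kept their call. Lanes 4 and 5 alone, with 1 wild-type library, gave 238 higher and 395 lower, of which 491 were shared with the 872. All lists called in MEP passed again with the length trend removed. The granule median moved from -0.36 to -0.12 (5 members lower), and 25 erythroid genes were called higher in place of 17. The G2 and M phase list (adjusted p = 0.0217) and the sex-linked list (0.0457), both lower, passed then too.

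**Figure D3:**
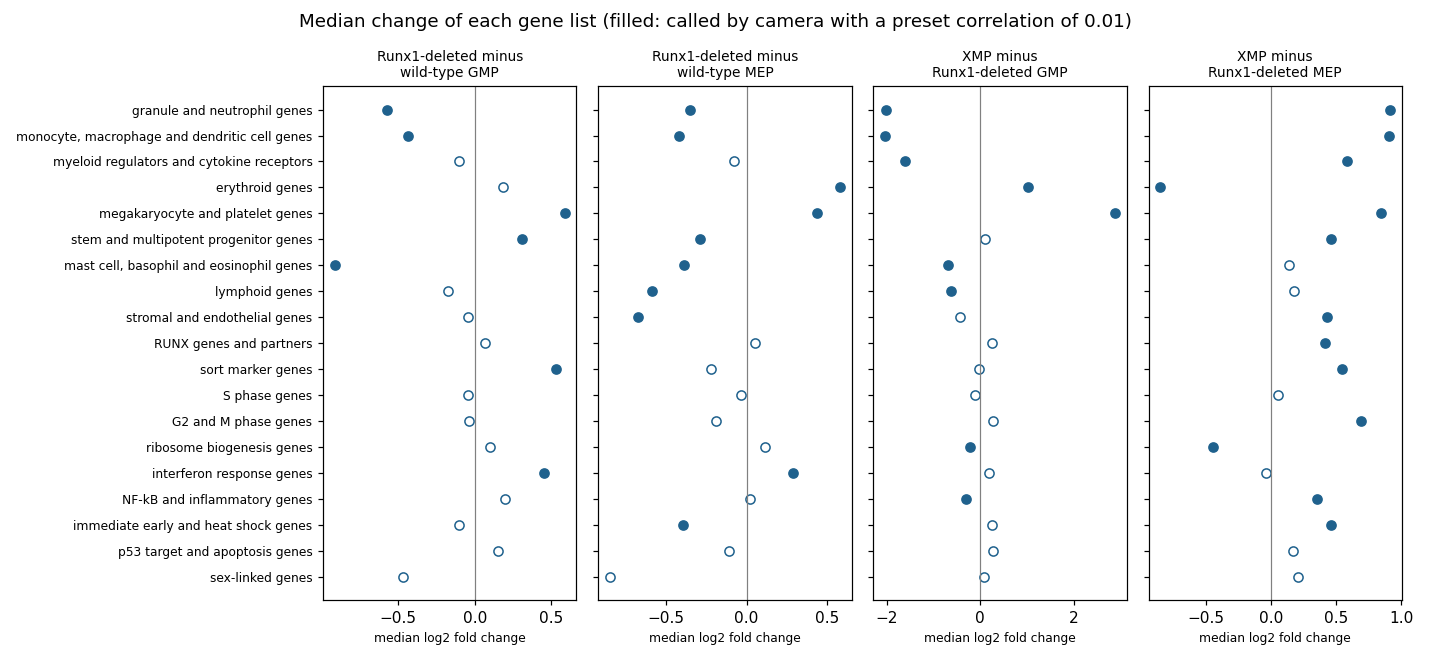
Median log2 fold change of the tested members of 19 gene lists, for Runx1-deleted minus wild-type GMP, Runx1-deleted minus wild-type MEP, XMP minus Runx1-deleted GMP and XMP minus Runx1-deleted MEP. Filled points passed the camera test at the preset inter-gene correlation, and with an estimated correlation 0 of the 114 pairs of list and contrast passed.

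The effects in the 2 gates were then compared directly. Of the genes changed in both GMP and MEP, 120 were higher in both Runx1-deleted groups (13.6 would be by independent draws), 97 were lower in both (9.10), and 3 went in opposite directions. Independent draws do not allow for what the 2 comparisons share besides Runx1. The lane went with the genotype, fully in GMP and in part in MEP, and sex-linked levels went with it in both. Part of the overlap can come from these. Scin, Csrp3, Cd63 and Prss34 fell in both gates, and Treml1 and Kdr rose in both. Across genes the Pearson correlation of the effects was 0.607 and the Spearman correlation 0.646. With the length trend removed, which the effects share, they were 0.534 and 0.525. The 217 genes changed in the same direction became 276 with the length trend removed and 99 without wild-type GMP replicate 2. They became 107 and 109 without Runx1-deleted GMP replicates 1 and 2, 130 and 114 without Runx1-deleted MEP replicates 1 and 2, and 1041 without wild-type MEP replicate 2.

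**Figure D4:**
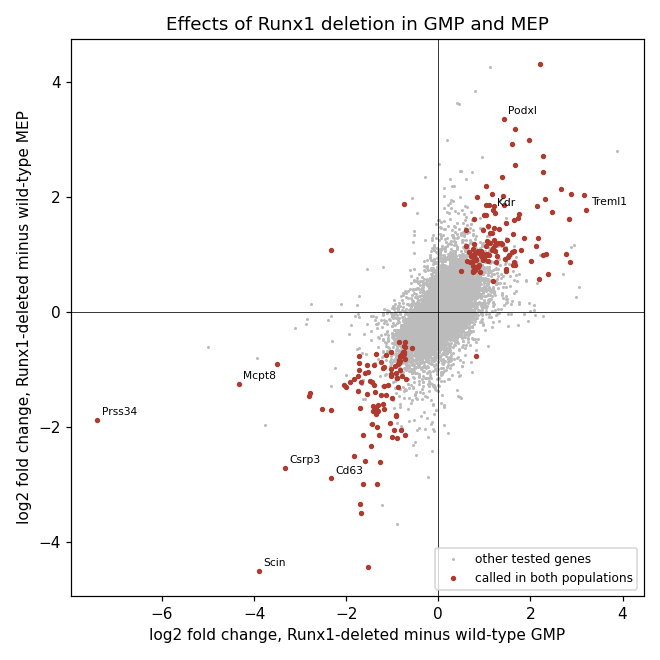
Log2 fold change of Runx1-deleted over wild-type cells in GMP (horizontal) and MEP (vertical) for 10905 genes, with genes called in both gates in red. Most of the red points lie in the lower left and upper right, where both effects have the same sign.

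The Runx1 effect differed between GMP and MEP for 190 genes (104 with the higher effect in GMP, 86 in MEP; 1096 at an unadjusted p under 0.05), and for 250 (152 and 98) with the length trend removed. F2r rose in GMP and stood at 0.44 in MEP (difference 2.61 ± 0.24, adjusted p = 0.000393). Ptgs1, cyclooxygenase 1, stood at 2.27 and -0.07 (difference 2.34 ± 0.25, adjusted p = 0.000904). Alox5, 5-lipoxygenase, fell in GMP (-2.32) and rose in MEP (1.07, adjusted p = 0.0142), with a difference of -3.40 ± 0.32 (adjusted p = 0.000393). Hpn stood at 0.45 in GMP and rose in MEP (3.62; difference -3.17 ± 0.28, adjusted p = 0.000346). Nkg7 stood at -1.52 in GMP and -4.44 in MEP (difference 2.92 ± 0.44, adjusted p = 0.00786). The count was 71 without wild-type GMP replicate 2, 87 and 55 without Runx1-deleted GMP replicates 1 and 2, 92 and 67 without Runx1-deleted MEP replicates 1 and 2, and 342 and 475 without wild-type MEP replicates 1 and 2. The split turned with these last libraries: 253 higher and 89 lower effects in GMP without replicate 1, and 152 and 323 without replicate 2. For 3 lists that did not pass here the median and the camera direction differed. These were granule genes (median 0.15 and mean 0.10, direction down) and monocyte genes (0.06 and -0.12, down) for the difference of effects, and RUNX genes (0.06 and -0.04, down) for wild-type GMP against MEP.

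XMP, sorted here from Runx1-deleted marrow alone, were compared with both other Runx1-deleted groups to ask which they resemble. Against Runx1-deleted GMP most of the granule genes were lower. Mpo was 4144 ± 568 RPKM in GMP and 65.4 ± 16.3 in XMP (log2 -5.98 ± 0.23, adjusted p = 8.19e-08). Elane, neutrophil elastase, was 1130.0 ± 152 and 17.7 ± 0.40 (log2 -5.91 ± 0.25, adjusted p = 1.17e-07) and Ctsg 1397 ± 149 and 22.5 ± 3.39 (log2 -5.90 ± 0.18, adjusted p = 3.76e-08). The myeloid regulators Irf8 (93.8 ± 23.8 and 4.9 ± 0.715; log2 -3.99 ± 0.23, adjusted p = 3.86e-07) and Cebpa (46.4 ± 3.84 and 2.56 ± 0.174; log2 -3.73 ± 0.18, adjusted p = 1.54e-07) were lower too. Platelet genes were far higher in XMP, with Pf4, platelet factor 4, at 6.88 ± 6.01 in GMP and 253 ± 136 in XMP (log2 5.15 ± 0.49, adjusted p = 1.69e-05). Treml1 stood at 17.2 ± 4.12 and 303 ± 50.8 (log2 4.07 ± 0.21, adjusted p = 2.09e-07) and Thbs1 at 3.02 ± 3.04 and 161 ± 29.6 (log2 5.56 ± 0.44, adjusted p = 4.05e-06).

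By list, 36 of 40 megakaryocyte genes were higher in XMP than in Runx1-deleted GMP and 0 lower (median 2.89, adjusted p = 6.71e-29, adjusted p = 0.189 with an estimated correlation). Likewise 25 of 44 erythroid genes were higher and 0 lower (median 1.03, adjusted p = 2.08e-17, adjusted p = 0.189 with an estimated correlation). Lower in XMP were 21 of 26 granule genes (median -2.02, adjusted p = 3.58e-22, adjusted p = 0.0647 with an estimated correlation) and 19 of 22 monocyte genes (median -2.04, adjusted p = 2.44e-16, adjusted p = 0.195 with an estimated correlation). Of 25 myeloid regulators 19 were lower and 1 higher (median -1.62, adjusted p = 3.83e-14, adjusted p = 0.0647 with an estimated correlation). Of the mast cell list 14 were lower and 5 higher (median -0.69, adjusted p = 0.000127, adjusted p = 0.32 with an estimated correlation). Of the lymphoid list 5 were lower and 1 higher, adjusted over the list alone 8 and 1 (median -0.62, adjusted p = 0.000981, adjusted p = 0.288 with an estimated correlation). Of the NF-kB list 11 were lower and 2 higher (median -0.31, adjusted p = 0.00727, adjusted p = 0.47 with an estimated correlation). The ribosome biogenesis list was lower, with 1 of 44 members called (median -0.21, adjusted p = 0.0189, adjusted p = 0.817 with an estimated correlation; 0.0825 and 0.0735 without Runx1-deleted GMP replicate 1 and XMP replicate 2). Of the 2143 genes that differed, 1063 were higher and 1080 lower in XMP (3079 at an unadjusted p under 0.05). The count was 1381 and 1417 without Runx1-deleted GMP replicates 1 and 2.

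Against Runx1-deleted MEP, XMP held less of the erythroid and more of the myeloid and platelet transcripts. Ermap was 106 ± 10.3 RPKM in MEP and 6.42 ± 2.74 in XMP (log2 -3.90 ± 0.31, adjusted p = 0.000109) and Car1 354 ± 29.3 and 31.2 ± 21.2 (log2 -3.63 ± 0.40, adjusted p = 0.00054). Pklr, the pyruvate kinase of liver and red cells, was 45.1 ± 11.8 and 2.34 ± 2.29 (log2 -3.96 ± 0.44, adjusted p = 0.000579). Of the erythroid genes 23 were lower, but 5 were higher, adjusted over the list alone 30 and 8 (median -0.85, adjusted p = 7.39e-14, adjusted p = 0.24 with an estimated correlation). The 5 include Slc4a1 (0.934 ± 0.097 and 4.34 ± 0.223; log2 1.47 ± 0.16, adjusted p = 0.000449) and Alas2, the first enzyme of heme synthesis in red cells (1.71 ± 0.026 and 6.75 ± 2.89; log2 1.46 ± 0.25, adjusted p = 0.00482). Mpo was 7.58 ± 1.63 in MEP and 65.4 ± 16.3 in XMP (log2 2.94 ± 0.23, adjusted p = 9.53e-05), and Fcgr2b 8.21 ± 1.3 and 66 ± 11 (log2 2.86 ± 0.20, adjusted p = 9.53e-05). Csf2rb, the shared beta chain of the IL-3, IL-5 and GM-CSF receptors, was 4.98 ± 0.473 and 26.6 ± 9.31 (log2 2.17 ± 0.23, adjusted p = 0.000407).

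By list, 12 of 26 granule genes were higher in XMP than in Runx1-deleted MEP (median 0.92, adjusted p = 2.39e-11, adjusted p = 0.189 with an estimated correlation). So were 10 of 22 monocyte genes (median 0.91, adjusted p = 4.42e-10, adjusted p = 0.288 with an estimated correlation) and 8 of 25 myeloid regulators (median 0.58, adjusted p = 2.76e-05, adjusted p = 0.189 with an estimated correlation). Of 40 megakaryocyte genes 17 were higher (median 0.84, adjusted p = 4.23e-12, adjusted p = 0.315 with an estimated correlation) and of 34 stem cell genes 11 (median 0.46, adjusted p = 0.000127, adjusted p = 0.288 with an estimated correlation), with 0 lower in each of these 5 lists. The RUNX list had 7 of 18 higher (median 0.41, adjusted p = 0.00422, adjusted p = 0.518 with an estimated correlation). The stromal and endothelial list had 2 of 6 (median 0.43, adjusted p = 0.0177, adjusted p = 0.32 with an estimated correlation). The G2 and M phase list was higher with 1 of 42 members called (median 0.69, adjusted p = 8.50e-09, adjusted p = 0.518 with an estimated correlation). The ribosome biogenesis list was lower with 2 of 44 (median -0.45, adjusted p = 7.22e-14, adjusted p = 0.32 with an estimated correlation). The sort marker list was higher, with 3 of 9 members higher (median 0.54, adjusted p = 0.02, adjusted p = 0.249 with an estimated correlation; 0.0582 and 0.0631 without wild-type MEP replicates 1 and 2). The NF-kB list was higher, with 1 of 26 members higher and 1 lower (median 0.35, adjusted p = 0.0207, adjusted p = 0.518 with an estimated correlation; 0.119 without Runx1-deleted MEP replicate 1), and so was the immediate early and heat shock list, with 5 of 21 members higher (median 0.46, adjusted p = 0.0189, adjusted p = 0.65 with an estimated correlation; 0.0821 and 0.0803 without Runx1-deleted MEP replicate 2 and XMP replicate 1). In all, 844 genes differed, 560 higher and 284 lower in XMP (2163 at an unadjusted p under 0.05). The count was 403 and 375 without Runx1-deleted MEP replicates 1 and 2, 305 and 351 without XMP replicates 1 and 2, and 1460 and 1462 without wild-type MEP replicates 1 and 2. The split was 626 higher and 526 lower with quantile normalization, and 204 and 171 without Runx1-deleted MEP replicate 2.

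On a scale from 0, the Runx1-deleted MEP level, to 1, the Runx1-deleted GMP level, XMP stood at a median of 0.138 (interquartile range 0.0271 to 0.30) over 385 genes that part GMP from MEP in both genotypes. The 262 genes high in GMP had a median of 0.156 and the 123 genes high in MEP a median of 0.0328, with an interquartile range of -0.282 to 0.443. The 2 XMP libraries alone stood at 0.150 and 0.115. Quantile normalization of the values gave 0.0932, a median still nearer to MEP.

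Some genes were not between the other 2 groups but beyond both. XMP held 225 genes above both Runx1-deleted GMP and MEP and 23 below both. Simulated unchanged groups with the same libraries gave 0 such genes in 20 runs. Where no group differs an adjusted test calls almost no gene, so this 0 does not measure what the shared libraries add. Independent lists of the same sizes would share 54.6 and 28.1, so the 23 lie under the independent value. The 2 contrasts share the XMP libraries, with too few to split, so part of the excess of the 225 over 54.6 can come from them. Among those above were Itga2b (78 ± 9.08, 211 ± 11.1 and 667 ± 21.5 RPKM in GMP, MEP and XMP) and the stem cell transcription factor Meis1 (30.1 ± 1.07, 33.5 ± 2.18 and 109.5 ± 4.56). Tuba8, a tubulin chain, was 10.8 ± 0.07, 21.2 ± 0.249 and 95.5 ± 0.316. Below both were Slc22a4, a carnitine and ergothioneine transporter (9.48 ± 1.23, 8.84 ± 2.71 and 0.971 ± 0.206), and Gatm, an enzyme of creatine synthesis (50.1 ± 9.48, 46.7 ± 6.62 and 15 ± 2.49). The count of 248 was 157 without Runx1-deleted GMP replicate 1, 130 and 111 without Runx1-deleted MEP replicates 1 and 2, 76 and 114 without XMP replicates 1 and 2, and 445 without wild-type MEP replicate 1 or 2. Quantile normalization gave 261 above and 70 below, and lanes 4 and 5 alone 404 and 63.

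The deposited table also carries the authors' own test between groups. At their false discovery rate under 0.05 it lists 215 genes for GMP, 180 for MEP, 869 for XMP against Runx1-deleted GMP, 381 for XMP against Runx1-deleted MEP and 721 for wild-type GMP against wild-type MEP. Of these, 97, 122, 752, 241 and 685 were also called by limma.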

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

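The differences of effect in this part were planned tests; the tests of the explanations for the globin, megakaryocyte and gene-length patterns were chosen only after those results were seen.

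The effect of Runx1 deletion differed between GMP and MEP by the interaction term for 190 genes. Among the largest, the GMP effect minus the MEP effect was 2.92 for Nkg7, 2.61 for F2r, 2.34 for Ptgs1, 2.31 for Vim (adjusted p = 0.0549 without Runx1-deleted GMP replicate 2), -5.53 for Prss34, -4.39 for Gzmb, -3.40 for Alox5, -3.22 for St3gal6 and -3.17 for Hpn. With voom on the recovered reads the calls of Prss34, Gzmb and St3gal6 ended (adjusted p = 0.104, 0.206 and 0.164). Prss34 fell in both gates (log2 -7.41 in GMP and -1.88 in MEP), in MEP from a low level. As log2(RPKM + 1) understates falls from low levels, part of its difference can come from the scale. The same can hold for the mast cell, basophil and eosinophil list, where 20 of 28 members were higher in wild-type GMP than in wild-type MEP. Members with a called higher and lower effect in GMP were 1 and 2 of 44 erythroid and 6 and 0 of 34 stem cell genes. They were 2 and 0 of 6 stromal and endothelial and 2 and 7 of 28 mast cell genes. For megakaryocyte genes they were 4 and 3 of 40, and for lymphoid genes 0 and 0 of 12. By list the median difference was -0.59 for erythroid genes (adjusted p = 7.31e-05, adjusted p = 0.47 with an estimated correlation; 0.0597 without wild-type MEP replicate 2), 0.66 for stem cell genes (5.37e-09 and 0.189) and 0.54 for stromal and endothelial genes (0.00195 and 0.266). It was -0.39 for mast cell, basophil and eosinophil genes (3.27e-05 and 0.311; 0.0681 without wild-type MEP replicate 2). For megakaryocyte genes it was 0.51 (0.0202 and 0.789; 0.108, 0.266 and 0.103 without wild-type GMP replicate 1, Runx1-deleted GMP replicate 2 and wild-type MEP replicate 2). For lymphoid genes it was 0.33 (0.0298 and 0.459; 0.302, 0.208, 0.438 and 0.0663 without wild-type GMP replicate 1, Runx1-deleted GMP replicate 2, wild-type MEP replicate 1 and Runx1-deleted MEP replicate 1).

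Globin transcripts were higher in Runx1-deleted GMP. For cells of the MEP gate, the globin gene that needs the smallest share of them would need 120% of the sample by group means. This share does not allow for the spread between libraries, so it cannot exclude them. Cells of the XMP gate with the average profile of that gate are excluded as the whole source. With the spread between libraries allowed for, the globins need at least 21.5% of them by the median. Of 35 other abundant XMP genes 29 allow less, even if GMP made none of their transcript. A partial share, or cells of either gate richer in globin than its average, stays open. RNA of late erythroid cells, which the lin- gate is meant to remove, is a candidate source: the ratio of Alas2 to Hba-a1 stayed within a 2.18-fold range over 10 libraries while Hba-a1 itself ranged 28.7-fold, although Slc4a1 to Hba-a1 ranged 12.3-fold. A change of globin expression within GMP after loss of Runx1 stays open and was not tested apart from this.

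Megakaryocyte genes were higher in Runx1-deleted GMP. A difference in length bias is excluded as the whole cause of the list result. Once the length trend was taken out the list passed camera at the preset correlation (median 0.54, adjusted p = 6.56e-08), with 12 members called higher. Whether these are the same 12 members as before was not compared. For the 12 called genes, the values argue against cells of the XMP gate with its average profile as the whole cause. These genes were chosen because they rose in the same libraries, which can raise the share they need. For the list as a whole such cells are therefore not excluded. The called genes need at least 7.16% of them by the median. The lowest shares that other abundant XMP genes allow were 0.840% for Gm15915, 2.20% for Ache and 3.03% for Mtss1l. In all, 8 of 21 other abundant XMP genes allow less than 7.16%, even if GMP made none of their transcript. This test replaced the percent of those genes that rose by under 2.21% (33.3%), whose limit was set after the shares were seen and moved from 25% to 50%, which changed its verdict. A smaller share of XMP cells could account for part of the rise. Of the called genes Mfsd2b and Slc14a1 need the least, 1.49% and 2.36%, and both lie above the 0.840% that Gm15915 allows. A rise within GMP after loss of Runx1 is a hypothesis found and tested on the same libraries.

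Long genes were higher and short genes lower in Runx1-deleted cells. The wild-type MEP library of lane 5 stood at 0.14 (log2, longest minus shortest genes), within the -0.003 to 0.31 of Runx1-deleted MEP, and that of lane 3 at -1.02. As lane 5 holds a single wild-type MEP library, loss of Runx1 in MEP stays open. A library or sequencing batch that goes with the lane is a candidate explanation. Taken on the difference of each gene, longest minus shortest was 1.12 between the wild-type MEP libraries of lanes 5 and 3. On the same measure the genotypes in GMP differed less (0.64). In GMP the 0.64 cannot be told apart from loss of Runx1, because no wild-type GMP library was run in lanes 4 or 5.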

How the results depend on the processing

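Group weights, voom on the recovered reads, removal of the length trend and lanes 4 and 5 alone were chosen only after the results were seen; the other alternatives were planned. Of 479 calls, each of a named gene or list in 1 contrast, 258 were kept under all alternatives run, 221 were lost under 1 or more, and 0 reversed. All 55 list calls are among the 221, since 0 of them passed with an estimated correlation. The 258 are thus calls of genes only. The counts of genes depend on the settings below. All contrasts share 1 estimate of the spread, to which the wild-type MEP replicates add most. The SD of their log2 difference was 0.519, against 0.197 in Runx1-deleted GMP. How much of each shift comes from this was not tested.

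A mean of at least 5 RPKM gave 196 genes in GMP, 412 in MEP, 63 for the difference of effects, 1200 for XMP against Runx1-deleted GMP, 1380 for wild-type GMP against MEP, 147 beyond both and 90 shared by GMP and MEP. An absolute log2 fold change of at least 1 gave 326, 445, 1214 (XMP against GMP), 422 (XMP against MEP), 1290 (wild type) and 103 (beyond both). Only the groups compared gave 1925, 340, 3216 (XMP against GMP) and 467 (beyond both). Group weights gave 2023, 219, 65 (difference), 3679, 1501, 1325 (wild type) and 513 (beyond both); the weight was 0.272 for wild-type MEP and 2.86 for Runx1-deleted GMP. For the difference of effects a pseudocount of 0.1 gave 80 and voom 53. Lanes 4 and 5 alone gave 1542 for XMP against MEP and 467 beyond both. With an estimated correlation 0 of 55 list calls remained. The position of XMP was 0.0932 with quantile normalization and 0.187 with a fold of at least 2. Quantile normalization split the GMP genes into 306 higher and 306 lower.

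Without 1 library the counts ran from 233 to 1729 in GMP, 361 to 3427 in MEP, 55 to 475 for the difference, 1381 to 2790 for XMP against GMP, 305 to 1462 for XMP against MEP, 1636 to 3315 for wild type, 76 to 445 beyond both and 99 to 1041 shared. The position ran from 0.115 to 0.151 and the list calls from 47 (without wild-type MEP replicate 2) to 63. The replicate block gave 552 genes in GMP and 844 in MEP, and the library set block 708 and 1066. The deviations of libraries of the same set correlated at 0.297 to 0.782 in 6 pairs of groups and at -0.147 to 0.0586 in the 4 pairs with wild-type GMP, so a shared set effect outside wild-type GMP stays open, and the labels do not say that the numbers mark a batch.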

Other observations

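The comparisons in this part were chosen only after the data were seen, apart from the fit that gives their adjusted p.

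Surface antigens named by CD number parted XMP from both other Runx1-deleted groups in a few cases. Of 48 tested genes 2 were above both, Cd9, a tetraspanin of platelets and stem cells (26.1, 76.9 and 162 RPKM in Runx1-deleted GMP, MEP and XMP), and Cd180, a TLR-like receptor (10.95, 5.30 and 25.3), and 1 was below both, Cd82 (23.5, 22.0 and 8.48). Below GMP and above MEP were 6 genes, among them Cd63, Cd93 and Cd52, and 1, Cd59a, was above GMP and below MEP (5.89, 50.4 and 22.8). Cd24a was lower in XMP than in MEP (241.8 and 52.4), and Cd34 was lower in XMP than in GMP (216 ± 9.62 and 17.7 ± 3.57). In all, 14 were below GMP alone, 7 above GMP alone, 2 above MEP alone and 1 below MEP alone, and 14 were called against neither.

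Among genes of at least 5 RPKM in each of the higher libraries, those at least 4-fold lower in each of the 6 Runx1-deleted libraries than in each of the 4 wild-type ones were Scin (14.1 to 30.8 RPKM in wild type and 0.0867 to 0.210 in Runx1-deleted libraries), Csrp3, a muscle LIM protein (13.9 to 21.9 and 0.624 to 2.57), and Khdrbs3, an RNA-binding protein (6.005 to 7.65 and 0.175 to 1.42). By the same rule 0 genes were at least 4-fold higher throughout. Among the 210 splits of the 10 libraries into 4 and 6, 4 gave as many lower genes, the real one included.

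Wild-type GMP replicate 2 held 4 genes at least 5-fold above all other libraries, among them Gm5148 (611 RPKM), Snhg9 (193) and Wdr89 (56.9). The other 9 libraries held 0 such genes each. Xist was 9.91 and 1.54 RPKM in wild-type GMP, 101.8 and 58.2 in Runx1-deleted GMP, 2.90 and 31.1 in wild-type MEP, 54.6 and 109.5 in Runx1-deleted MEP, and 60.0 and 124 in XMP. The sum of 4 Y-chromosome genes was 20.9 and 25.1, 16.0 and 8.65, 17.4 and 38.3, 6.06 and 11.9, and 8.06 and 14.9 in the same order, so both kinds of transcript were present in each library. Xist was at most 31.1 RPKM in the wild-type libraries and at least 54.6 in the Runx1-deleted ones. The Y-chromosome sum was at least 17.4 in the former and at most 16.0 in the latter. Sex-linked levels thus went with the genotype, and a difference in the sex of the cells cannot be told apart from it.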
